A study of Mus musculus with 6 samples.

How the data were processed

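RNA of CD4 T cells from mouse liver was extracted with the Direct-zol RNA MicroPrep kit, per the labels' protocols, and counted with the nCounter assay, per the series title. The groups were taken from the sample titles and descriptions, 3 control (Chow) and 3 MASH (FFC) libraries, and the series' design text calls the 3 per group biological replicates. How the cells were sorted, the diet's length and the panel's name are not given in the sources used here.

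The authors deposited 1 table of log2 values for 750 genes in 6 libraries. How these values were normalized is not given in the sources used here. In each library, 2 to the power of every value was a whole multiple of 1 step (100% of values, to within 0.02 of a whole number), so that the values are log2 of a count times a scale factor. The factors were 0.774, 0.707 and 1.10 in control libraries 1 to 3 and 1.18, 1.26 and 1.11 in MASH libraries 1 to 3, and their log2 values average to 0 over the libraries. What they were made from, and whether a background was subtracted before counts were scaled, is not stated. The table holds no control probes, and only 1 gene of the reference list, Mtmr14. Median counts were 378.5, 417.5 and 360 in control and 367.5, 393.5 and 319 in MASH. Probe sequences were not used here, so that probes of multigene families such as the H2, Klra and interferon alpha genes are open to cross-hybridisation.

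Gene names were matched to the symbols of the RefSeq annotation of GRCm38.p6, of which 734 were current symbols, 16 were synonyms and 0 were unmatched. No coordinates are given because the deposited table names no genome build.

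Genes with a mean of at least 20 on the linear scale over the 6 libraries were tested, 748 of 750. The deposited log2 values entered limma 3.58.1 in R 4.3.3 unchanged, with lmFit and eBayes (trend and robust off), both groups in 1 fit and no covariate; tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Gene lists for T cell programmes and for other cells of the liver were fixed from textbook knowledge, 35 in all, of which 26 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 26. Camera was also run with the correlation estimated for each list, and fry gave directional and mixed tests. A camera call compares the members with the other genes, so that a list can rank lower with a median above 0. Lists share members, so that the same gene can count in several. Also in another list were 8 of 16 tested cytotoxic, 11 of 15 inhibitory receptor, 8 of 13 Th1, 9 of 12 regulatory T cell and 4 of 7 NK genes. Counts "adjusted over the list alone" used the gene p-values of the members only. The comparison with random lists matched on count was chosen after the data were seen.

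The lists, the tests and the rule for named genes were set before the data were examined. The rule took the 12 largest increases and 12 largest decreases among genes past the threshold with groups apart (7 decreases qualified), and up to 4 members with the smallest p of each list past camera and of the main T cell lists. It also took a set of markers whatever their values. Some genes are not reported here. Gzmb, Tnfrsf17, Cr2, Tg, Prkcq, Csk and H2-DMb2 are named outside that rule and were chosen after their values were seen, as was the set of 10 genes used chiefly in other organs, of which 9 were tested.

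On simulated data for the comparison of MASH with control (748 genes, 50 simulations, 200 changed genes), limma recovered 19.7% of genes changed 1.5-fold, 71.3% of those changed 2-fold and 98.4% of those changed 4-fold, with 3.63% false among the calls. Camera called a list of 20 genes moved by 0.8 (log2) in 100% of simulations and an unmoved list in 0%. These simulated camera calls used an unadjusted p under 0.05, not one adjusted over the 26 lists. The simulated genes varied independently of each other, whereas the correlation estimated within the real lists reached 0.83 (interferon response). These rates therefore need not hold for genes and lists that vary together.

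The replicates were compared before averaging. The first principal component held 67.2% of the variance and separated the groups. On it control 3 (-1.4) and MASH 3 (2.4) were the nearest pair across the groups. On the second, with 16.4% of the variance, these 2 libraries lay far apart, at 5.0 and -12.2.

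The alternatives set in advance were pseudocounts of 10 and 0.1, no filter and a mean of at least 50, centring on the median, scaling by reference genes, quantile normalization, the replicate number as a block, each library left out in turn, trend and robust eBayes, a threshold of 0.1, and a fold minimum of 1.5. Alternatives added after the data were seen were voom on the recovered counts, a mean count of at least 200, a background floor, libraries with a scale factor over 1 only, control 3 and MASH 3 both left out, and cyclic loess. The floor was the mean plus 2 SD of the genes of other organs in each library. Because the deposited values are log2 values and not counts, the count models planned for that case were not used.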

Results

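RNA of CD4 T cells from mouse liver was counted for 750 genes on the nCounter platform, which hybridises barcoded probes to RNA and counts the barcodes without amplification. There were 6 libraries in 2 groups. The control group held 3 samples labelled Chow and the MASH group held 3 labelled FFC, and the series describes the 3 in each group as biological replicates. MASH is in this field the usual abbreviation of metabolic dysfunction-associated steatohepatitis, and FFC a usual name of a diet high in fat, fructose and cholesterol; the labels spell out neither. The deposited values were log2 of whole-number counts times 1 scale factor per library. The recovered counts summed to 820998, 900322 and 726836 in control libraries 1 to 3 and to 689432, 693640 and 623212 in MASH libraries 1 to 3. With 3 libraries per group the precision was limited.

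The design implies 1 comparison, hepatic CD4 T cells in MASH against control. On the deposited scale the gene with the largest difference was Havcr2, a co-inhibitory receptor, which was 9.74-fold higher in MASH (log2 5.49 ± 0.42 in control and 8.77 ± 0.10 in MASH, SD, n = 3 each). Gzma, a granule protease of cytotoxic lymphocytes, was 9.30-fold higher. Gzma differed more than Havcr2 in 8 of 21 alternatives, among them quantile normalization (log2 2.76 against 2.65), cyclic loess (2.86 against 2.53) and a background floor, where Havcr2 stood at 1.74, and the fold of Havcr2 rests on control counts below those of genes of other organs. Ifng, the gene of interferon gamma, was 3.63-fold higher. The chemokine genes Ccl8 and Pf4 rose 7.23-fold and 5.98-fold, and genes typical of macrophages, such as the complement gene C1qa and the Fc receptor genes Fcgr1 and Fcgr4, rose 4.78-fold, 4.35-fold and 4.19-fold. For Fcgr1 the log2 difference was 2.12, against 2.72 without MASH 3, and it did not pass under quantile normalization (adjusted p = 0.062). The chemokine gene Ccl2 was 3.40-fold higher in control, and Ccr7, a homing receptor of naive and central memory T cells, 1.98-fold.

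In limma's moderated test 137 of 748 tested genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 130 were higher and 7 lower in MASH. Of the 137, 76 exceeded the background floor in at least 1 library, and the others lay under it in all 6. The adjusted p was 0.00065 for Havcr2, 0.016 for Gzma, 0.013 for Ifng and 0.030 for Ccl2. The 137 depended on single libraries: 7 genes passed without control 1, 2 without control 2, 1 without MASH 1 and 1 without MASH 2, against 290 without control 3 and 234 without MASH 3. Havcr2 passed in each of these 6 fits, and every other gene named here as risen or fallen failed in at least 1 of them. The groups did not overlap for 257 genes higher and 32 lower in MASH, or 38.6% of the tested genes. Chance gives 10% for a single gene, which is no benchmark for genes that vary together. Each MASH scale factor was above each control one, so that a gene with equal counts in all libraries would also be apart.

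The scale of the deposited values mattered for the direction. The median gene was 0.43 (log2) higher in MASH, and the mean log2 scale factor was -0.24 in control and 0.24 in MASH. With each library centred on its own median, which removed 0.39, 144 genes passed, 108 higher and 36 lower, so that the share of higher calls went from 94.9% to 75%. Of the 130 higher calls 104 were also called higher after centring, as were all 7 lower calls in their direction. Quantile normalization gave 30 higher and 23 lower calls and cyclic loess 37 and 28. Across the deposited, centred, quantile, cyclic loess and voom scalings, 34 genes passed each time in 1 direction, 30 higher and 4 lower. Some genes named in this comparison as risen or fallen did not pass under quantile normalization, namely Ccl5, Ccl20, Ccr7, Cd3g, Cd4, Cd40lg, Cd44, Cd244, Cr2, Csf2, Elane, Fcer1a, Fcgr1, Gbp2, Il18rap, Klrd1, Ltf, Maf, Ncr1, Nr4a2, Prdm1, Pros1, Stat4, Tnfrsf17 and Xcr1. Under cyclic loess Ccl20, Ccr7, Fcgr1, Gbp2, Klrd1, Nr4a2 and Stat4 of these passed and the others did not. The values after centring stand beside the deposited ones in what follows.

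**Figure D1:**
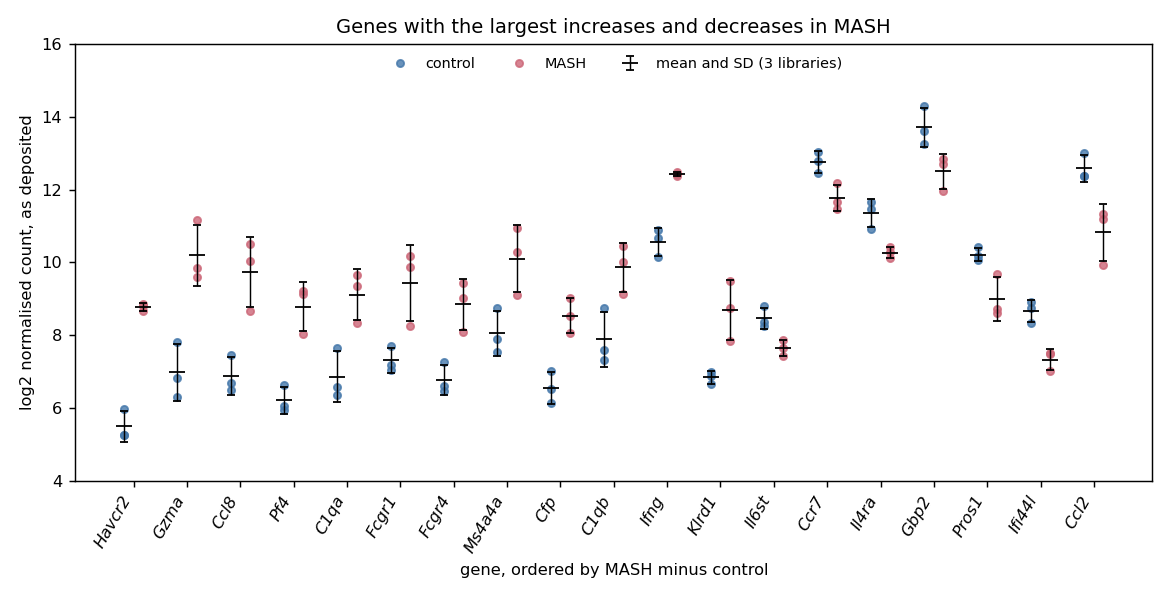
Log2 normalised counts as deposited (vertical axis) of the 12 genes with the largest increases and the 7 that fell, with 1 point per library, control in blue and MASH in red, and black marks for the mean and SD of 3 libraries. The groups do not overlap for any of these genes, and Havcr2 lies at 5.49 in control and 8.77 in MASH.

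The differences also went with the level of a gene. The median log2 difference was 0.83 over the 84 genes with a mean recovered count up to 100, 0.80 over the 144 between 100 and 200, and 0.08 over the 173 above 1000. Passing as higher in MASH were 27 of the 84, 46 of the 144 and 15 of the 173. Genes used chiefly in other organs, such as Tg of the thyroid, averaged 70.4, 70.6 and 73.7 counts in the control libraries and 97.2, 117.4 and 89.1 in the MASH libraries. Of 9 such genes tested 5 passed as higher in MASH, with a median difference of 0.96 over the 9. Havcr2 stood at 49, 54 and 57 counts in control, below that level, and at 343, 366 and 403 counts in MASH.

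**Figure D2:**
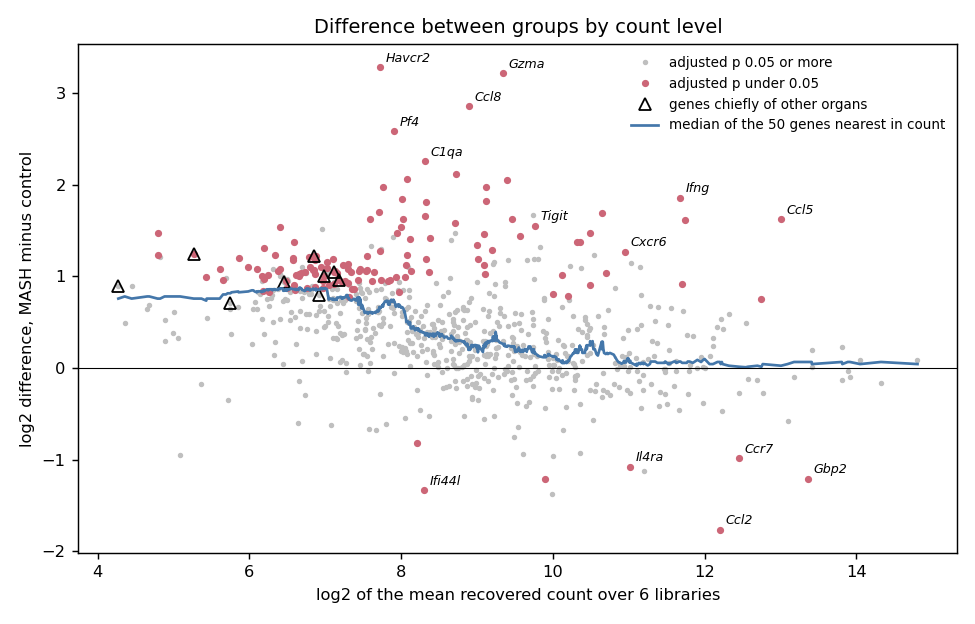
Log2 difference between MASH and control (vertical axis) against log2 of the mean recovered count over 6 libraries (horizontal axis), with 1 point per gene, genes past the test in red, genes chiefly of other organs as triangles and the median of the 50 genes nearest in count as a line. The line falls from about the level of the triangles, whose median is 0.96, to near 0.08 among genes with over 1000 counts.

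Since camera compares a list with genes of every level, the median of each list was also set against 10000 random lists matched on mean count. Of the 8 lists that passed camera, the cytotoxic and macrophage lists lay at percentile 100, inhibitory receptors at 99.96, neutrophil genes at 99.94 and NK genes at 98.26. On the lower side the dendritic cell list lay at percentile 1.59, naive and central memory genes at 5.75 and interferon response genes at 45.83. Among lists that did not pass camera, Th17 genes lay at percentile 99.51, chemokines at 99.36 and B cell genes at 0.44.

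Genes of cytotoxic effector function were higher in MASH as a group. Of 16 tested members 9 rose and none fell, over all genes and adjusted over the list alone, or 8 after centring, and the list passed camera as higher than the other genes (adjusted p = 0.0037; adjusted p = 0.91 with an estimated correlation). Gzma rose by 3.22 ± 0.49 (log2, SE; 2.83 after centring) and Ifng by 1.86 ± 0.25 (1.47 after centring). Klrk1, an activating receptor of NK and T cells, rose by 1.63 (1.24 after centring), Fasl, a death ligand, by 1.42 (1.03 after centring), and Ccl5, a chemokine of effector T cells, by 1.62 (1.24 after centring). The granzyme gene Gzmb differed by 0.65 (adjusted p = 0.14). Without control 3 the list no longer passed (adjusted p = 0.12). Markers of NK cells moved in the same direction, but near background. Ncr1 stood at 54.7 mean counts in control and 82.3 in MASH (1.08, adjusted p = 0.030). Under quantile normalization Ncr1 differed by 0.29 (adjusted p = 0.29). In every library it lay below the mean count of the genes of other organs, whose median difference was 0.96. Klrb1 (0.52, adjusted p = 0.19) and Klra1 (0.89, adjusted p = 0.055) did not pass in limma. Cd8a differed by 0.46 (adjusted p = 0.18; -0.03 under quantile normalization) and Cd8b1 by 0.75 (adjusted p = 0.070).

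Inhibitory receptors and exhaustion genes formed another group that was higher in MASH. Of 15 tested members 8 rose and none fell, or 10 adjusted over the list alone and 7 after centring, and the list passed camera (adjusted p = 0.0051; adjusted p = 0.91 with an estimated correlation). Havcr2 rose by 3.28 (95% interval 2.69 to 3.87; 2.90 after centring), and by 1.74 with values under a background floor raised to it (adjusted p = 0.014). Tigit, a co-inhibitory receptor, rose by 1.55 (1.17 after centring), Cd96, a receptor related to it, by 1.54 (1.15 after centring), and Nr4a2, a nuclear receptor induced by antigen receptor signals, by 1.03 (0.64 after centring). Cd96 had only 47, 62 and 55 counts in control and 117, 139 and 88 in MASH, under the background floor in all 6 libraries. Pdcd1, the best known inhibitory receptor of exhausted T cells, differed by 1.32 ± 0.41 (adjusted p = 0.055), with values of 10.46, 11.16 and 9.40 in MASH and a mean of 9.02 in control. Without control 3 this list did not pass either (adjusted p = 0.12). Macrophages can also express Havcr2, and macrophage genes were higher in the same libraries. In MASH 3, the lowest MASH library for 13 of 16 macrophage genes after centring, Havcr2 had its highest count, 403. That contrast rests on 1 library and does not decide the source of Havcr2.

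Of 22 tested members of the T cell receptor complex and its signalling 3 rose and none fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.18). They were Ptpn22, a phosphatase that restrains receptor signalling, at 1.03 (0.65 after centring), Cd3g at 0.91 (0.53 after centring) and Cd4 at 0.79 ± 0.22 (0.40 after centring). After centring only Ptpn22 of the 3 passed, with an adjusted p of 0.23 for Cd3g and 0.20 for Cd4, and 3 members passed as lower, among them Prkcq (-0.70) and Csk (-0.63). Cd3e differed by 0.32 (adjusted p = 0.36; -0.06 after centring) and Zap70 by 0.47 (adjusted p = 0.13). Among 13 activation genes 4 rose, or 5 adjusted over the list alone and 3 after centring, with no camera call (adjusted p = 0.74): the costimulatory receptor Tnfrsf9 (1.12; 0.73 after centring), Cd40lg, the ligand by which CD4 T cells help B cells (1.44; 1.05 after centring, adjusted p = 0.067), Nr4a2 and the adhesion receptor Cd44 (1.03; 0.64 after centring). Under quantile normalization Cd44 stood at 0.27 (adjusted p = 0.24).

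Among the helper programmes, 5 of 13 Th1 members rose, or 6 adjusted over the list alone and 4 after centring, without passing camera (adjusted p = 0.093). In camera the list passed in 7 of 22 alternatives, with adjusted p from 0.015 to 0.91, and it passed fry's directional test, which does not compare with other genes (adjusted p = 0.017). They were Havcr2, Ifng, Il18rap, the signal transducer Stat4 (1.19; 0.80 after centring) and Cxcr6, a receptor of liver-resident lymphocytes (1.27; 0.88 after centring). The Th1 master regulator Tbx21 differed by 0.62 (adjusted p = 0.071; -0.01 under quantile normalization). Of 9 Th2 members Maf rose by 1.12 (0.73 after centring) and Il4ra, a receptor chain for the Th2 cytokine of that name, fell by 1.08 (-1.47 after centring), also adjusted over the list alone (camera adjusted p = 0.055). Gata3 differed by -0.20 (adjusted p = 0.58), Il4 by -0.62 (adjusted p = 0.33) and Il10 by 0.93 (adjusted p = 0.083). Of 14 Th17 members the chemokine gene Ccl20 (1.19; 0.80 after centring) and the growth factor gene Csf2 (1.48; 1.09 after centring, adjusted p = 0.081) rose, also adjusted over the list alone (camera adjusted p = 0.86). Il22 differed by 1.67 (adjusted p = 0.10; 1.07 without control 1 and 2.37 without control 2) and Il23r by 0.92 (adjusted p = 0.057).

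The regulatory T cell list was not set apart from the other genes by camera (adjusted p = 0.62). Of its 12 members 11 were above 0, with a median of 0.52, and fry's directional test, which does not compare with other genes, passed (adjusted p = 0.017). The 2 that rose were Tigit and Prdm1, also adjusted over the list alone. Foxp3, which defines these cells, stood at 8.905 ± 0.66 in control and 9.003 ± 0.52 in MASH (SD, n = 3 each; limma adjusted p = 0.89), and its sign turned after centring (-0.29). Il2rb differed by 0.59 (adjusted p = 0.077). Of 13 follicular helper members Cd40lg and Maf rose and Il6st fell, or 4 and 1 adjusted over the list alone and 1 and 1 after centring (camera adjusted p = 0.86). Of 9 tissue residency members Cxcr6, Ccl5 and Prdm1 rose, or 4 adjusted over the list alone and 2 after centring (camera adjusted p = 0.62). Prdm1, a regulator of terminal differentiation, stood at 0.83 (0.44 after centring, adjusted p = 0.055), and Rbpj at 0.62 (adjusted p = 0.069).

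Naive and central memory genes ranked lower than the other genes in camera, while against lists matched on count they lay at percentile 5.75. Of 10 tested members 2 fell and none rose, also adjusted over the list alone, and the list passed camera as lower (adjusted p = 0.0027; adjusted p = 0.91 with an estimated correlation). Ccr7 fell by 0.99 ± 0.27 (-1.37 after centring) and Il6st, the shared signalling chain of several cytokine receptors, by 0.82 (-1.21 after centring). The quiescence factor Foxp1 differed by -0.53 (adjusted p = 0.13; -0.92 after centring, adjusted p = 0.017). The list's median was 0.01 and its mean -0.15, against a median of 0.43 over all tested genes. Under cyclic loess the adjusted p of the list was 0.072.

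Interferon response genes ranked lower than the other genes in camera, but against lists matched on count they lay near the middle, at percentile 45.83, and by library the values were uneven. Of 36 tested members 1 rose and 2 fell, or 1 and 1 adjusted over the list alone and 1 and 6 after centring, and the list passed camera as lower (adjusted p = 0.0022; adjusted p = 0.91 with an estimated correlation), with a median of 0.16 and a mean of 0.15 that were positive. Ifitm1, an antiviral membrane protein, rose by 1.59 (1.20 after centring), while Ifi44l fell by 1.34 (-1.72 after centring) and the guanylate-binding protein gene Gbp2 by 1.21 (-1.60 after centring). Cxcl9, a chemokine induced by interferon gamma, differed by -0.93 (adjusted p = 0.059), and by -1.31 after centring (adjusted p = 0.017); it also passed under quantile normalization, cyclic loess and voom. Without MASH 3 the camera adjusted p of the list was 0.99, and under quantile normalization 0.41.

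Markers of other cells were measured beside the T cell genes. Of 16 macrophage, Kupffer cell and monocyte genes 6 rose and none fell, or 11 adjusted over the list alone, and the list passed camera as higher (adjusted p = 0.022; adjusted p = 0.91 with an estimated correlation). C1qa rose by 2.26 ± 0.44 (1.87 after centring), C1qb by 1.98 (1.59 after centring), Fcgr4 by 2.07 (1.68 after centring) and Lilrb4a, an inhibitory receptor that activated T cells can also express, by 1.61 (1.23 after centring). C1qa had 105, 135 and 183 counts in control and 557, 640 and 288 in MASH. Outside the lists Ms4a4a, a membrane protein gene of macrophages, rose by 2.06 (1.67 after centring) and the complement regulator Cfp by 1.98 (1.59 after centring), while Pros1, a ligand of receptors that macrophages use to clear dying cells, fell by 1.22 (-1.60 after centring).

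Of 17 neutrophil, mast cell and basophil genes 10 rose and none fell, or 12 adjusted over the list alone and 9 after centring (camera adjusted p = 0.0051; adjusted p = 0.91 with an estimated correlation). Mpo and Elane, enzymes of neutrophil granules, rose by 1.22 and 1.07 (0.84 and 0.68 after centring), Ltf by 1.08 (0.69 after centring) and Fcer1a by 1.05 (0.66 after centring). Under quantile normalization Mpo stood at 0.54 (adjusted p = 0.044), while Elane at 0.28, Ltf at 0.33 and Fcer1a at 0.35 did not pass (adjusted p = 0.24, 0.30 and 0.15). Ltf stood at 67.3 and 101.3 mean counts in the 2 groups, close to the genes of other organs. The list's median was above that of lists matched on count (percentile 99.94), but among genes with a mean count of at least 200 the list did not pass (adjusted p = 0.35). Of 7 NK, NKT and gamma-delta T cell genes 4 rose, or 6 adjusted over the list alone and 3 after centring (camera adjusted p = 0.026; adjusted p = 0.91 with an estimated correlation): Klrd1 (1.85; 1.46 after centring), Ncr1 (0.69 after centring), Cd244 (0.94; 0.56 after centring) and Il18rap (1.54; 1.15 after centring, adjusted p = 0.086). Cd244 stood at 0.25 under quantile normalization (adjusted p = 0.29). That list did not pass without control 3 (adjusted p = 0.11) or without MASH 3 (adjusted p = 0.058), nor under quantile normalization (adjusted p = 0.10).

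Dendritic cell and antigen presentation genes passed camera as lower (adjusted p = 0.043; adjusted p = 0.91 with an estimated correlation), although the 2 of 16 members past the gene test had risen, also adjusted over the list alone, and the median of 0.09 and the mean of 0.07 were positive. These were Ccl19, a ligand of Ccr7 (1.70; 1.31 after centring), and Xcr1, a receptor of cross-presenting dendritic cells (1.00; 0.61 after centring). Under quantile normalization Xcr1 stood at 0.23 (adjusted p = 0.31). Its counts were 61, 56 and 60 in control and 78, 93 and 82 in MASH, below the mean of the genes of other organs in every library. The class II loading gene H2-DMa differed by -0.97 (adjusted p = 0.078). After centring it passed as lower (-1.35, adjusted p = 0.018), as did H2-DMb2 (-1.33, adjusted p = 0.023), beside the 2 that rose. Itgax differed by 0.66 (adjusted p = 0.057; -0.05 under quantile normalization). The list did not pass without control 3 (adjusted p = 0.27) or without MASH 3 (adjusted p = 0.16), nor after centring (adjusted p = 0.060). Of 13 B cell genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.14); they were Tnfrsf17 and Cr2, at 0.88 and 0.85. After centring neither passed (adjusted p = 0.10 and 0.051), while 3 members of the list passed as lower. Of 8 hepatocyte genes 0 passed in limma, 0 adjusted over the list alone and 0 under voom, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.62). Alb and Csf1r were not among the genes measured.

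**Figure D3:**
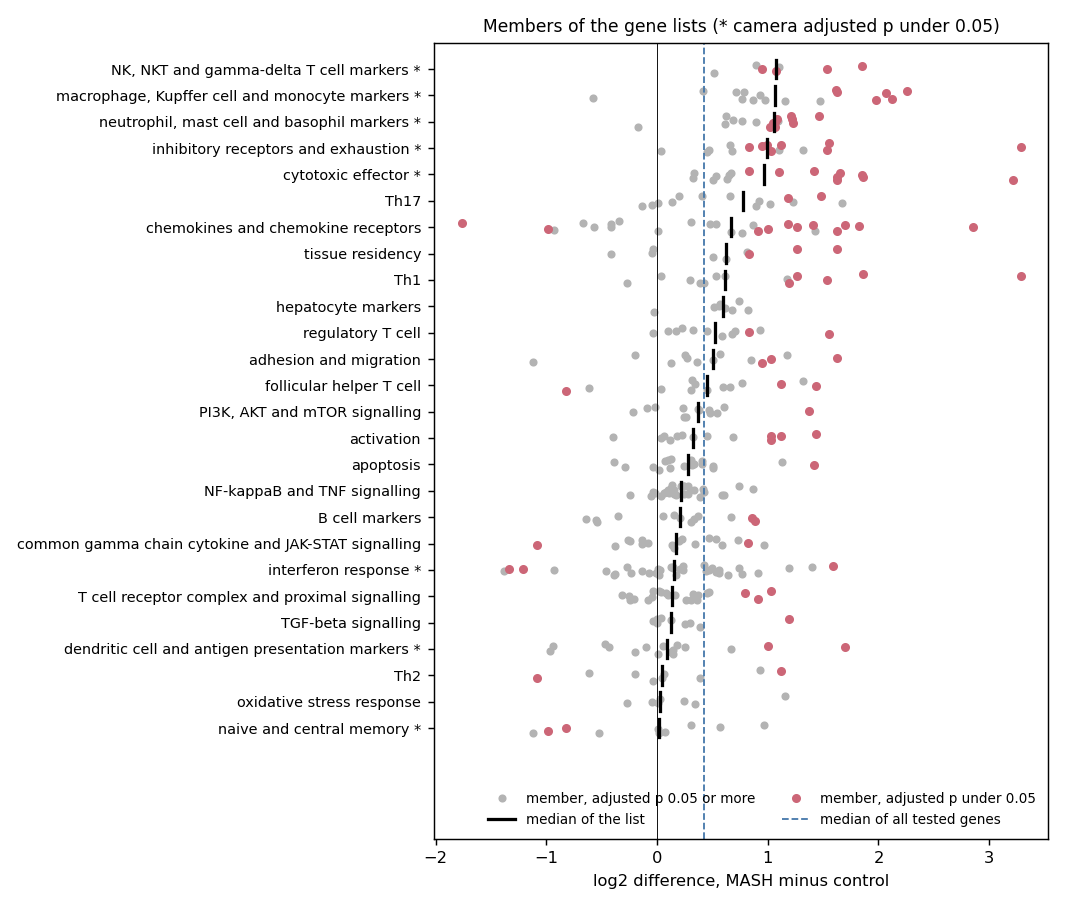
Log2 difference between MASH and control (horizontal axis) of the tested members of 26 gene lists, with 1 point per gene, members past the gene test in red, black bars for the median of each list and a dashed line for the median of all tested genes at 0.43. The 5 lists with the highest medians, from 0.97 to 1.08, are the cytotoxic, inhibitory receptor, neutrophil, macrophage and NK lists, and the naive and central memory list has the lowest, 0.01.

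The remaining lists did not pass camera. Their counts of risen and fallen members were 9 and 2 of 25 for chemokines and chemokine receptors (12 and 3 adjusted over the list alone; adjusted p = 0.65), 3 and 0 of 13 for adhesion and migration (4 and 0; adjusted p = 0.86) and 0 and 0 of 29 for NF-kappaB and TNF signalling (0 and 0; adjusted p = 0.28), where 2 had an unadjusted p under 0.05 in limma and 1 passed under voom. They were 1 and 0 of 18 for apoptosis (1 and 0; adjusted p = 0.52), 1 and 0 of 13 for PI3K, AKT and mTOR signalling (1 and 0; adjusted p = 0.97) and 0 and 0 of 7 for the oxidative stress response (0 and 0; adjusted p = 0.28), where 1 had an unadjusted p under 0.05 and 0 passed under voom. Common gamma chain cytokine signalling had 1 and 1 of 18 (0 and 1; adjusted p = 0.083) and TGF-beta signalling 1 and 0 of 9 (1 and 0; adjusted p = 0.52). After centring, chemokines had 9 and 3, apoptosis had 1 and 1, and in common gamma chain signalling the 1 that rose no longer passed and 3 fell. For chemokines the median was 0.24 above that of the other genes while camera ranked the list lower. Against lists matched on count the chemokine list lay at percentile 99.36. For follicular helper genes the median was 0.02 above that of the other genes and camera again ranked the list lower. Lists with under 5 tested members were not tested: 3 of 3 erythroid and platelet genes rose, 1 of 3 glycolysis genes, and none of 2 CD8 T cell genes, 3 endothelial and stellate cell genes, 2 amino acid genes or 1 fatty acid oxidation gene, of which 1 CD8 gene and the fatty acid oxidation gene passed adjusted over the list alone. No gene of the cell cycle, mitochondrial respiration or fatty acid and cholesterol synthesis lists was measured.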

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

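Of the alternatives reported here, voom, the count minimum of 200, the background floor, the choice of libraries by scale factor, the omission of control 3 with MASH 3 and cyclic loess were chosen after the data were seen. None of the 137 calls changed sign in any of the 21 alternatives in which it was tested. The alternative count model planned for unnormalized counts was not run because the values are log2. The sample titles do not say whether the replicate numbers pair the samples. Deviations from the group means of same-numbered libraries correlated at 0.02, -0.22 and -0.04, which with 3 libraries per group cannot exclude a pairing. With the replicate block, which leaves 2 residual degrees of freedom, 1 gene passed, 1 higher and 0 lower. Genes near the level of the other-organ genes, 70.4 to 117.4 counts per library, are limited by background. Except where stated, the cause was not tested.

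The 137 changed genes ranged from 1 to 290 with 1 library left out, the 130 higher from 1 to 284, the 7 lower from 0 to 6, and the 8 gene lists past camera from 5 to 10. Fewer libraries lower the power, but leaving out control 3 or MASH 3 raised the count. Median centring gave 36 lower. Scaling by the reference gene, Mtmr14 alone, gave 30 (24 higher, 6 lower), quantile normalization 53 (30 and 23), cyclic loess 65 (37 and 28) and voom 216 (191 and 25). A mean count of at least 200, with 520 genes tested, gave 34 (31 and 3), and the background floor, with 587 tested, 87 (83 and 4). Of the 137 calls, 76 were tested with the floor and 68 passed. Control 3 against the 3 MASH libraries, with 1 library standing for control and assumed to vary as the MASH group does, gave 0 in limma (0 higher, 0 lower; 73 at an unadjusted p under 0.05). Without control 3 and MASH 3 there were 475 (460 and 15). A threshold of 0.1 gave 246 (234 and 12). Lists past the threshold were 5 under cyclic loess, 0 with an estimated correlation and 20 in fry's mixed test, which does not compare a list with other genes.

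Reversals concerned genes that had not passed and lists. Cd3e was -0.064 after centring and -0.013 with the reference gene. Under quantile normalization Cd8a was -0.032, Itgax -0.053 and Tbx21 -0.0087, and under cyclic loess Itgax was -0.14 and Tbx21 -0.0055. Foxp3 was -0.29 after centring, -0.24 with the reference gene, -0.24 under quantile normalization, -0.16 under cyclic loess, -0.11 under voom and -0.58 with scale factors over 1 only; with 1 library left out Foxp3 ran from -0.22 to 0.44. Il4 was 0.14 with the background floor. For lists the direction is camera's, and the values are median differences from the other genes. Chemokines turned at 0.24 (centring, and with the reference gene), 0.21 (quantile), 0.16 (cyclic loess), 0.24 (voom) and 0.38 (scale factors over 1). Follicular helper genes turned at 0.024 (reference gene), 0.10 (quantile), 0.050 (cyclic loess), 0.17 (floor), 0.19 (count of 200) and 0.0016 (scale factors over 1), and hepatocyte genes at 0.017 (quantile), -0.055 (cyclic loess) and 0.074 (scale factors over 1). PI3K signalling turned at -0.046 (pseudocount of 10), 0.0068 (floor), 0.10 (count of 200) and 0.029 (cyclic loess), and Th17 at 0.36 (voom). Without control 3 and MASH 3, Th17 was -0.0062, activation -0.31, regulatory T cell -0.11 and interferon response -0.021. With 1 library left out PI3K signalling ran from -0.13 to 0.0057, Th17 from -0.25 to 0.60, activation from -0.32 to 0.15 and follicular helper genes from -0.047 to 0.16.

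In camera the cytotoxic list passed in 20 of 22 alternatives (shift 0.49 to 0.94), inhibitory receptors in 20 (0.48 to 0.73), macrophage genes in 20 (0.28 to 1.22) and naive and central memory genes in 20 (-0.56 to -0.22). Neutrophil genes passed in 18 (0.28 to 0.83), interferon response in 17 (-0.50 to 0.01), NK genes in 14 (0.27 to 1.28) and dendritic cell genes in 12 (-0.60 to -0.14). Of the other lists, Th1 passed in 7 (0.09 to 0.51), B cell genes in 5 (-0.81 to 0.22), Th2 in 3 (-0.71 to -0.12) and common gamma chain signalling in 2 (-0.50 to 0.02). T cell receptor and NF-kappaB genes each passed in 1, after centring. Fry's directional test, which does not compare a list with other genes, passed for the cytotoxic, inhibitory receptor, NK, Th1, activation and regulatory T cell lists.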

Other observations

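The tests of explanations in this part were chosen after the results were seen, except the count of splits of the libraries. The members named next were also chosen after their values were seen. Chemokine genes moved in both directions. Ccl21a, a lymphoid stromal chemokine that attracts cells bearing Ccr7, rose by 1.82 ± 0.26 (log2, SE; limma adjusted p = 0.013), with Ccl19, the other ligand of Ccr7, while Ccr7 itself fell. Ccl8, Ccl5 and Ccl20 rose and Ccl2 fell, from 12.59 ± 0.37 in control to 10.82 ± 0.77 in MASH (SD, n = 3 each). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 1.69 (adjusted p = 0.047; 1.31 after centring, adjusted p = 0.083) and Nos2, the inducible nitric oxide synthase, by 1.34 (adjusted p = 0.033; 0.96 after centring). Under quantile normalization neither passed (adjusted p = 0.13 and 0.062). The hypoxia factor gene Hif1a rose by 0.75 (adjusted p = 0.043), but its value of 0.36 after centring did not pass (adjusted p = 0.32), nor did it under quantile normalization (adjusted p = 0.11) or cyclic loess (adjusted p = 0.056). As with the 137 genes together, these calls were lost without some single libraries.

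Interferon genes divided the MASH libraries. After centring each library, MASH 3 was the lowest of the 3 MASH libraries for 30 of 36 interferon response genes, against 275 of all 748 tested genes. Its median gap to the mean of MASH 1 and 2 was -0.90 for that list and 0.04 for all tested genes. The values of single genes that follow are as deposited, without centring, and the library medians were 8.76, 8.96 and 8.47 in MASH 1 to 3. Mx1 stood at 9.66, 10.17 and 7.14 in MASH 1 to 3 and at 7.22, 7.73 and 7.83 in control 1 to 3, and Ifi44 at 9.49, 9.84 and 7.38 in MASH and 9.88, 10.58 and 10.40 in control. MASH 3 was also the lowest for 13 of 16 macrophage genes, with a median gap of -0.62, and for 11 of 15 inhibitory receptor and exhaustion genes, with a median gap of -0.41. Within that list Tigit stood, as deposited, at 10.62, 10.80 and 9.82 in MASH 1 to 3. Havcr2, at 8.66, 8.85 and 8.81 as deposited, and Ifng, at 12.48, 12.41 and 12.37, showed no such gap.

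The median gene and the genes with few counts were higher in MASH. The mean log2 scale factors differed by 0.49 between the groups, and on recovered counts without them the median log2 difference was -0.061. Since 1 factor per library moves every gene alike, the factors fix that value, and it does not decide whether they are the source of the median's rise. Genes chiefly of other organs rose 0.88 more than genes with over 1000 counts. They lay only 0.14 above genes of similar count, however, and were chosen after some values were seen. A larger part of counts without target RNA in the MASH libraries therefore cannot be told apart from another source of the rise at few counts. A change in the amount of RNA per cell or in the number of cells stays open, untested, since neither is given in the sources used here.

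Macrophage genes were higher in MASH. The list's median lay at percentile 100 of 10000 random lists matched on count, so that it rose more than genes of similar mean count. The random lists drew genes singly, while the members varied together (estimated correlation 0.80), and matching used the mean over both groups. The comparison therefore cannot decide whether the general rise of genes with few counts was the whole cause. Macrophages or their RNA in the libraries cannot be told apart from a change in the T cells. Of the members 93.75% lay above the median of the 50 genes nearest in count, but the place of the list's median among matched lists already called for a large share, and either source would give it. Of the 16 members 2 are in another list, and the most abundant of those that rose, Lilrb4a, had 2157 mean counts in control and 4684 in MASH, while Ly6c1, with 11569 and 5917, and Cd14, with 389.0 and 371.7, did not pass. A CD4 sort would remove most macrophages, and how the cells were sorted is not given in the sources used here.

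Cytotoxic effector genes were higher in MASH. Here too the list's median lay at percentile 100 of matched random lists, above genes of similar mean count. The same limits apply (estimated correlation 0.32), so that the rise of genes with few counts is not excluded as the cause. NK cells cannot be told apart from a change in CD4 T cells. The median of Ncr1, Klrb1 and Klra1 lay only 0.049 above genes of similar count (0.25 for Ncr1 alone). These markers stood near background, where a small share of NK cells could be hidden. CD8 T cells cannot be told apart either: the larger of the values of Cd8a and Cd8b1 was 0.075 above such genes, but both had a baseline, 317 and 202 mean counts in control, that could hide a small share. A change in the CD4 T cells with MASH stays open.

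The 6 libraries form 10 splits into 3 and 3. The real split gave 137 genes and the highest other split 0, and 1 of 10 splits gave as many genes; 10 splits are too few for a share under 0.05.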
